A study of Mus musculus with 7 samples.

How the data were processed

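The labels describe 7 RNA-seq libraries of CD11b+ migratory DCs sorted from the mediastinal lymph node of B6 mice 24 hours after intranasal house dust mite allergen with LPS, 3 from adults and 4 from infants. Each library was placed in its group by the age its label gives. Per the labels' protocols, RNA was isolated with a column kit and libraries were prepared by a sequencing provider with standard Illumina methods. The submitters' processing notes name the mm10 build, TopHat, TopHat2 2.0.14 and 2.1.0, Cufflinks 2.2.1.0, and Cuffdiff and Cuffnorm 2.2.1, with no role or order. Which program made the tables used here, its annotation and whether it counted by strand are not given in the sources used here.

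Each deposited file held 1 row per gene for 1 library. Per the file headers, the authors gave whole read counts per gene, split into exon, exon-exon and intron reads and into unique and total reads. The authors' RPKM values were total exon reads per kilobase of exon, scaled to the mapped reads of the library, which was checked on the files: the ratio of reads to RPKM and exon length was constant within each file. The authors' TPM values summed to 1000000 in each file and were not used in a test. A further expression column of the authors equalled unique exon reads plus junction reads that map to several places, and was not used. Every row had a gene name. Of the gene identifiers, 99.2% were in GENCODE M21 for GRCm38, and 99.96% of those overlapped the position given there, so coordinates are reported as mm10.

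All tests used the total exon read counts as deposited. These include reads that map to more than 1 place, 8.93% to 9.45% of exon reads per library. Totals were 18022302 to 22316484 reads, so 3 reads correspond to 0.134 to 0.167 CPM in a library before TMM scaling. That covers counting error only. Genes were kept with edgeR's filterByExpr by group, leaving 12261. Counts were scaled by TMM and fitted with edgeR 4.0.16 (glmQLFit with robust estimation and glmQLFTest, age as the term) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. Positive log2 fold changes mean higher in infants. Standard errors are the fold change divided by the square root of the test's F. CPM values use the TMM-scaled library sizes. The common biological coefficient of variation was 0.232, and the median log2 fold change of all genes was 0.0016. Replicates within a group differed far beyond sampling noise, with a chi-square per degree of freedom of 17.9 to 152, so each library counted as 1 replicate.

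The tests, the alternatives, 39 gene lists (19 processes, 16 cell types, 4 on sample quality) and the rule for named genes were set before the data were examined. Lists with at least 5 tested members were tested with limma 3.58.1, by camera on the signed z of the edgeR test with a preset correlation of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry, both on log2 CPM, stand beside it. Fry's p asks whether a list's genes move on balance one way and does not compare them with other genes. In the lists, 4 places had no matching gene in the files. Older symbols were used where the files have them. Itgam appears as the first of its entries.

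Named genes followed a rule with 3 parts. The first takes up to 10 genes each way with the widest fold change among those past the threshold, with an average log2 CPM of at least 3 and groups that do not overlap, leaving out predicted, immunoglobulin, T cell receptor and sex-linked names. The second takes up to 4 members with the smallest p of each called list and of the first 12 process lists, and up to 2 of each other list, of which the text gives fewer. The third takes 31 genes always named, of which 30 could be tested and 0 passed by edgeR, where 9 had an unadjusted p under 0.05, while DESeq2 called 3, Cd80, Tnfsf4 and Ccl17. A gene that this rule names and that fails the filter is given by its reads only. 1 gene that the rule names is not reported here.

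The alternatives were DESeq2 1.42.0, limma-voom, RLE, upper-quartile or no scaling factors, no filter on low counts, a filter of at least 5 CPM in at least 3 libraries, dispersion without robust estimation, the replicate number as a block, unique exon reads, limma-trend on the authors' RPKM as log2(RPKM + 1) for genes at 1 or more in at least 3 libraries, with a pseudocount of 0.1 or with no filter, removal of sex-linked, immunoglobulin and T cell receptor genes, stricter thresholds, and leaving out each library in turn. After the data were seen 3 were added: the log2 CPM of 4 Y-linked genes as a covariate, voom with a quality weight per library, and counts thinned at random to 18022302 reads per library. The tests were also tried on simulated counts, in 5 simulations with 200 genes changed. These used the means, library sizes and dispersions of the 12261 genes from the fit to the real counts. EdgeR recovered 10.0% of genes changed 1.5-fold, 50.8% at 2-fold, 88.8% at 4-fold and 95.2% at 8-fold, all with the right sign. A list moved by 0.5 on the log2 scale was called in 5 of 5 simulations and 0 of the other lists were called, though the simulated genes vary independently and the genes in the libraries do not. Figures were drawn with matplotlib from the tabulated values.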

Results

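RNA was sequenced from CD11b+ dendritic cells (DCs) that had migrated from the lung to the lymph node draining it, in C57BL/6-type (B6) mice. Dendritic cells are antigen-presenting cells that carry inhaled material to the node and prime T cells there. All animals had received house dust mite allergen together with lipopolysaccharide (LPS), a bacterial product sensed by Tlr4, through the nose 24 hours earlier. The cells were sorted from the mediastinal lymph node as CD11c+ cells with high MHC class II and CD11b, without B220, CD64 or CD103. There were 3 libraries from adults of 7 weeks and 4 from infants of 2 to 3 weeks. The adult libraries held 20064331 to 22316484 exon reads and the infant libraries 18022302 to 20377361. Of 48440 genes in the files, 12261 were measured well enough to test, and these took 99.9% of the reads. The labels do not say that each library came from separate animals, so p-values measure the spread between these libraries.

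The libraries differed within groups as well as between them. The first principal component took 36.5% of the variance and set infant 2, at 65.7, apart from the other 6 libraries, which lay between -22.3 and 8.59. Infant 2 also had 13539 CPM (read counts scaled to library size) of Malat1, a nuclear non-coding RNA, against 3108 to 3728 CPM in the other infants. On the first component infant 1, at -14.2, lay nearer to the adults, at -22.3 to -20.9, than to infants 3 and 4, at 8.59 and 4.45. The second component took 20.2% of the variance and set infant 1, at -44.9, apart from the other libraries, at -12.4 to 30.2. Adults 1 and 3 had 0 reads of Xist and 3428 and 4066 reads of 4 Y-linked genes, while adult 2 had 546 reads of Xist and 3 of the Y-linked genes. Every infant library held both, with 117 to 285 Xist reads and 340 to 1432 Y-linked reads. The labels do not say whether a library was made from 1 animal or from a pool. Reads of both Xist and Y-linked genes argue against 1 animal per infant library. The adult libraries each had the reads of 1 sex almost alone, so each could be 1 animal or a pool of 1 sex. If the infant libraries were pools of both sexes, their SDs measure the spread between pools and not between animals.

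**Figure D1:**
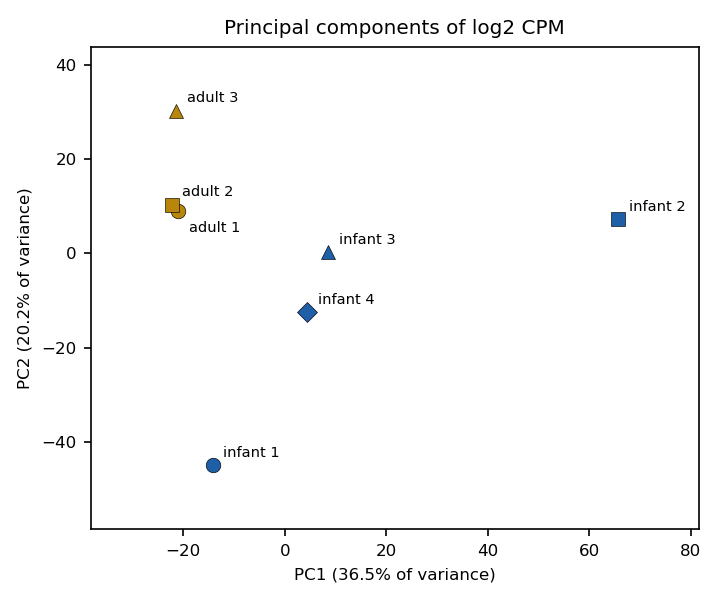
Principal components of log2 CPM over the tested genes, with 1 point per library (adults gold, infants blue; the symbol marks the replicate number); the axes are unitless scores with the share of variance in percent. Infant 2 lies at 65.7 on the first component, and the 3 adults lie between -22.3 and -20.9.

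The study asked which genes and signalling pathways differ between CD11b+ migratory DCs of infants and adults. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2 of the 12261 genes changed, 1 in each direction. Igf2bp3, an RNA-binding protein best known from fetal and embryonic tissue, rose from 0.198 ± 0.263 CPM in adults (SD, n = 3) to 17.9 ± 1.79 CPM in infants (SD, n = 4), a log2 fold change of 6.44 (SE 0.56, adjusted p = 0.00468 by edgeR). Its exon reads were 0, 11 and 2 in the adult libraries and 323, 355, 322 and 363 in the infant libraries. Rnf217, a ubiquitin ligase of the RING family, fell from 9.51 ± 1.64 CPM in adults (SD, n = 3) to 1.63 ± 0.149 CPM in infants (SD, n = 4), a log2 fold change of -2.54 (SE 0.24, adjusted p = 0.00468 by edgeR). For both genes every infant library lay on one side of every adult library.

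Igf2bp3 (ENSMUSG00000029814) is a protein-coding gene on the minus strand of chromosome 6, from 49085223 to 49214957 in mm10, with 8159 bp of exon. In infants 978 of its 1363 exon reads crossed an exon junction, and 412 further reads lay in its introns. In adults it had 13 exon reads, 7 of them across a junction, and 66 intron reads. Over all libraries 92.7% of its exon reads mapped uniquely. The plus-strand genes Malsu1 and Gm18010 overlap its span, and whether the counting used strand is not given in the sources used here. Rnf217 (ENSMUSG00000063760) is a protein-coding gene on the minus strand of chromosome 10, from 31493193 to 31609184 in mm10, with 11013 bp of exon. All of its 615 adult and 125 infant exon reads mapped uniquely, and 1 other gene, Gm7909, overlaps its span on the same strand. Rnf217 had an average log2 CPM of 2.36, below the floor of 3 set for named genes, and was named after its values were seen because only 2 genes passed.

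**Figure D2:**
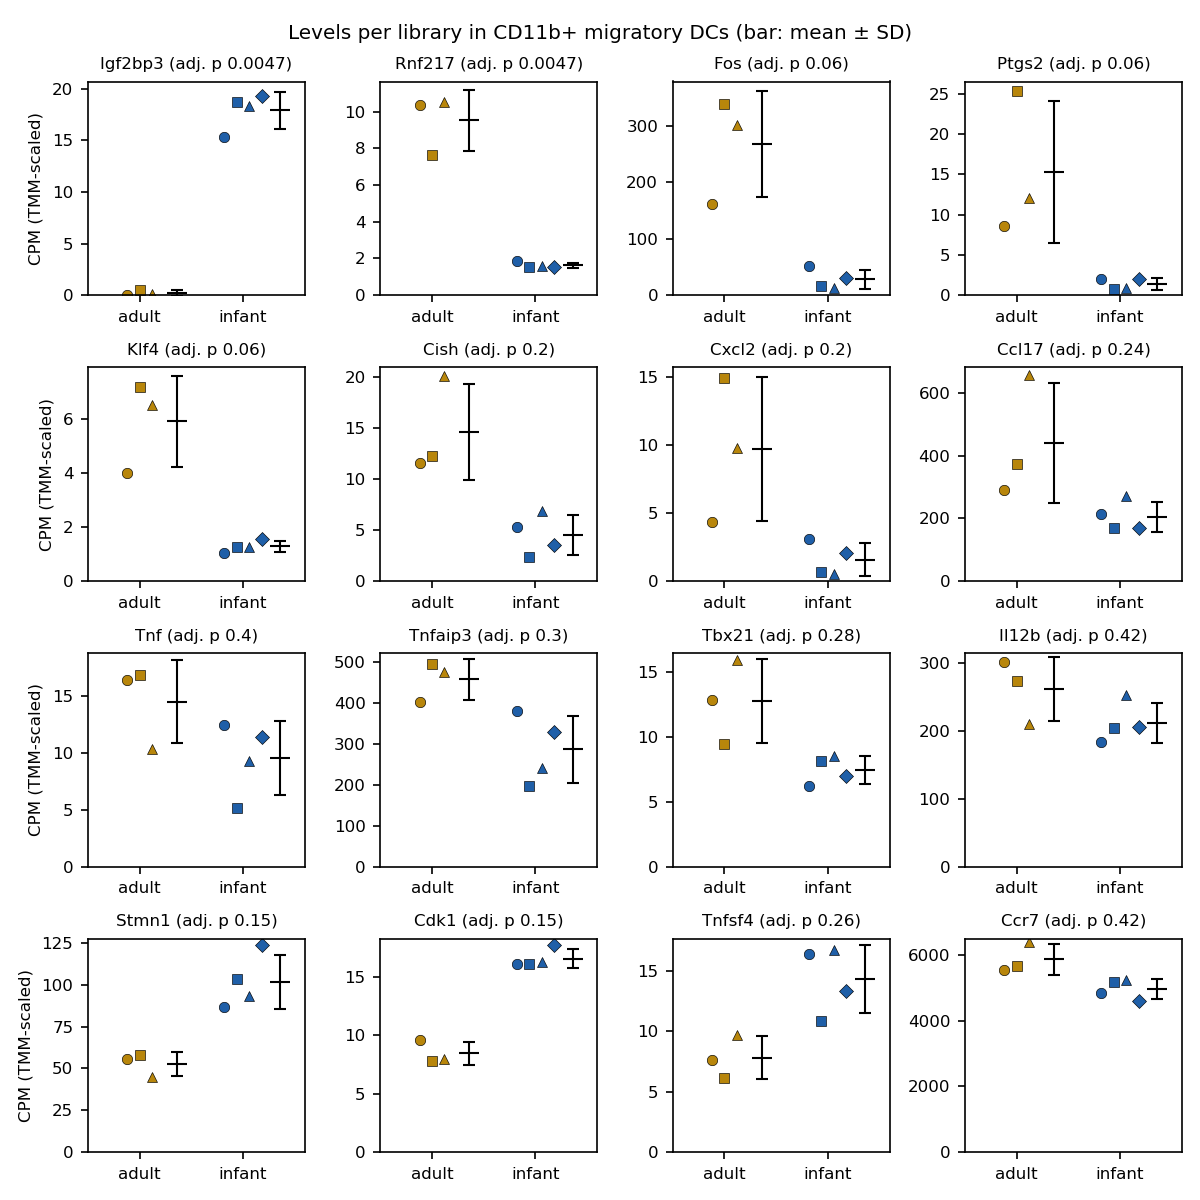
CPM per library, scaled by TMM, of 16 genes in adults (gold, n = 3) and infants (blue, n = 4), with the mean and SD as a black bar beside each group and the edgeR adjusted p above each panel. Igf2bp3 and Rnf217 pass the threshold, and Fos, Ptgs2 and Klf4 have adjusted p = 0.0605.

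At an unadjusted p under 0.05 there were 1626 genes. The groups did not overlap for 1906 genes (15.5% of those tested, where chance gives 5.71%), with infants above adults in 977 and adults above infants in 929. DESeq2 called 181 genes, 66 higher and 115 lower in infants, the edgeR pair among them, and limma-voom called 3, adding Fos. Leaving out 1 library moved the number of changed genes from 2 to 10 without adult 1, to 4 without adult 3, infant 1 or infant 2, and to 3 without adult 2, with Igf2bp3 and Rnf217 among them each time. In simulated data of the same size edgeR recovered 50.8% of genes changed 2-fold and 88.8% of those changed 4-fold. There 20% of DESeq2's calls were false against 6.42% of edgeR's. Each simulation changed 200 genes, and the simulated genes vary independently, which the genes in the libraries do not. These shares therefore cannot say how many large changes were missed here. Ptgs2, Fos, Cxcl2 and Klf4 changed over 4-fold (log2 fold changes -3.45, -3.26, -2.61 and -2.20) and did not pass by edgeR. Igf2bp3 and Rnf217, also over 4-fold, did pass.

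Gene lists fixed before the data were examined were tested as wholes. With camera and its preset correlation of 0.01, 12 of 32 lists were called, 10 lower and 2 higher in infants. Other splits of the libraries into groups of the same sizes called a median of 9.5 lists (1 to 19). The count of 12 therefore does not by itself set the ages apart. Estimated correlations in the called lists ran from 0.037 (GM-CSF and STAT5 signalling) to 0.334 (interferon-stimulated genes). No list held with an estimated correlation, and fry called 1. Fry's test for members that move in either direction passed for 9, of which 3 were not called by camera.

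**Figure D3:**
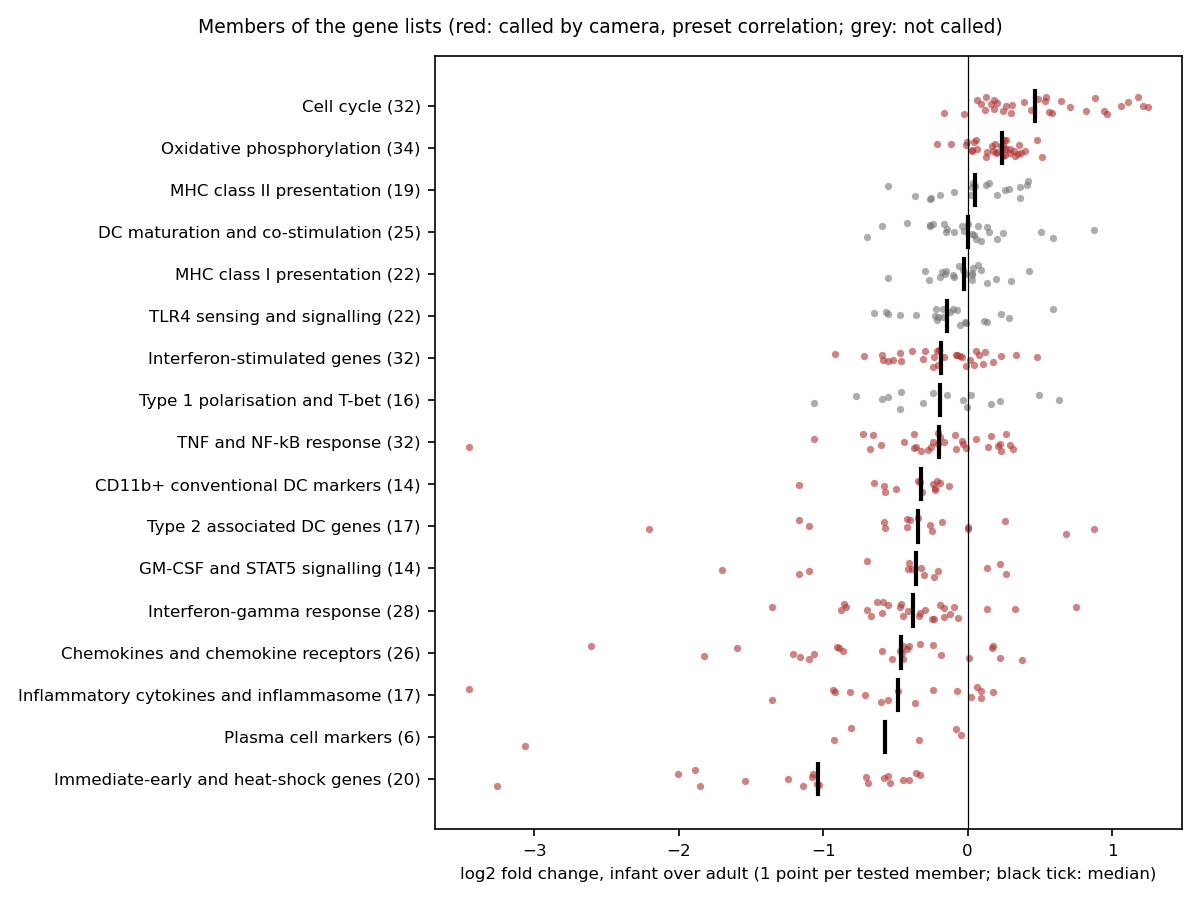
Log2 fold change of each tested member (points) and the median (black tick) of the lists called by camera and of the lists on DC activation; the number of tested members is in brackets. The medians of the called lists run from -1.03 for the immediate-early genes to 0.46 for the cell cycle.

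The TNF and NF-kB response, the axis named in the study's title, was lower in infants as a list (32 tested members, camera adjusted p = 0.0167; adjusted p = 0.699 with an estimated correlation). Adjusted over the list alone, Ptgs2 and Rel fell and none rose, and over all genes none of the 32 passed by edgeR, where 9 had an unadjusted p under 0.05 and DESeq2 called 2. Without adult 1 or infant 1, 4 members fell over the list alone. Tnf, the cytokine itself, was at 14.5 ± 3.62 CPM in adults (SD, n = 3) and 9.59 ± 3.24 CPM in infants (SD, n = 4), a log2 fold change of -0.60 (SE 0.30, adjusted p = 0.400 by edgeR). Of its receptors, Tnfrsf1a had a log2 fold change of -0.37 (SE 0.32) and Tnfrsf1b of -0.37 (SE 0.28). Ptgs2, which makes prostaglandins, went from 15.3 ± 8.84 to 1.39 ± 0.685 CPM, a log2 fold change of -3.45 (SE 0.46, adjusted p = 0.0605 by edgeR). Rel had a log2 fold change of -0.66 (SE 0.12), Nfkbiz of -1.06 (SE 0.32) and Tnfaip3, the NF-kB feedback inhibitor A20, of -0.67 (SE 0.21). Relb, at -0.08 (SE 0.14), and Icam1, at -0.21 (SE 0.17), lay closer to 0. Infant 2 stood apart for this list, with a mean centred log2 CPM of -0.38 against -0.08 to -0.0044 in the other infants and 0.11 to 0.26 in adults, and without it camera gave adjusted p = 0.0454. The immediate-early and heat-shock genes were also lower in infants (median log2 fold change -1.03).

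LPS sensing was not called. The TLR4 sensing and signalling list had a median log2 fold change of -0.14 over 22 members (camera adjusted p = 0.148). Tlr4 itself was low in both groups, at 4.11 ± 1.68 CPM in adults (SD, n = 3) and 3.49 ± 2.23 CPM in infants (SD, n = 4). Its co-receptor Cd14 had a log2 fold change of -0.65 (SE 0.25), and the adaptors Traf6 and Ticam2 of -0.55 (SE 0.19) and -0.47 (SE 0.17), while Tab1 was at 0.59 (SE 0.20). No member passed over all genes by edgeR or DESeq2, and 4 had an unadjusted p under 0.05.

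Inflammatory cytokines and inflammasome genes were lower in infants as a list (17 members, camera adjusted p = 0.00350; adjusted p = 0.512 with an estimated correlation), with 1 member, Ptgs2, falling when adjusted over the list alone. Il1b went from 202 ± 14.5 to 106 ± 44.1 CPM, a log2 fold change of -0.93 (SE 0.30), Il1a had one of -0.71 (SE 0.25) and Il6 of -0.48 (SE 0.18). Chemokines and their receptors were also lower as a list (26 members, camera adjusted p = 8.97e-06; adjusted p = 0.512 with an estimated correlation). Adjusted over the list alone, 7 fell and 1 rose, and those that fell numbered 2 without adult 2 and 3 without adult 3. Among them, Cxcl2, a neutrophil attractant, had a log2 fold change of -2.61 (SE 0.58), Ccl4 of -1.60 (SE 0.29), Ccl3 of -1.21 (SE 0.29) and Ccl17, which attracts Th2 cells, of -1.10 (SE 0.27). Ccl22 stood at 3126 ± 307 CPM in adults (SD, n = 3) and 2338 ± 653 CPM in infants (SD, n = 4), a log2 fold change of -0.42 (SE 0.22). Over all genes no member of either list passed by edgeR, where 4 cytokine and 11 chemokine members had an unadjusted p under 0.05, while DESeq2 called 1 of the cytokine list and 5 of the chemokines. The inflammatory members that fell over the list alone numbered 2 without infant 2 and 3 without infant 3.

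GM-CSF and STAT5 signalling genes were lower in infants (14 members, camera adjusted p = 0.000496; adjusted p = 0.447 with an estimated correlation), and 4 fell when adjusted over the list alone. These 4 were Cish, Pim1, Socs3 and Osm, with log2 fold changes of -1.70 (SE 0.35), -1.10 (SE 0.23), -1.17 (SE 0.27) and -0.69 (SE 0.21). Cish, a STAT5 target that restrains cytokine signalling, went from 14.7 ± 4.72 to 4.51 ± 1.96 CPM. The GM-CSF receptor chain Csf2rb was at -0.41 (SE 0.23), and none of the 14 passed over all genes by edgeR, where 7 had an unadjusted p under 0.05 and DESeq2 called 3.

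Type 2 associated DC genes were lower as a list (17 members, camera adjusted p = 0.00515; adjusted p = 0.537 with an estimated correlation), and adjusted over the list alone 2 fell and 1 rose. Klf4, a transcription factor needed for DCs that prime Th2 responses, went from 5.90 ± 1.68 to 1.28 ± 0.206 CPM (log2 fold change -2.20, SE 0.30, adjusted p = 0.0605 by edgeR). Tnfsf4, the ligand of OX40 on T cells, moved the other way, from 7.84 ± 1.79 to 14.3 ± 2.78 CPM (log2 fold change 0.87, SE 0.23, adjusted p = 0.261 by edgeR). Irf4 was at -0.57 (SE 0.31), Il4ra at -0.40 (SE 0.16) and Pdcd1lg2 at -0.26 (SE 0.13). Over all genes no member passed by edgeR, where 4 had an unadjusted p under 0.05, and 3 by DESeq2, and the members that fell over the list alone numbered 1 without adult 3, infant 1 or infant 2. The list's call was lost with library quality weights (adjusted p = 0.0666), and its adjusted p ran from 0.000148 to 0.0666 over 24 settings.

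The type 1 list was not called (16 members, camera adjusted p = 0.245). Tbx21, which encodes T-bet, went from 12.8 ± 3.23 CPM in adults (SD, n = 3) to 7.48 ± 1.07 CPM in infants (SD, n = 4), a log2 fold change of -0.77 (SE 0.22, adjusted p = 0.283 by edgeR). Every adult library lay above every infant library for this gene. Il12b, the p40 chain of IL-12, was at 261 ± 46.6 and 211 ± 29.4 CPM (log2 fold change -0.31, SE 0.16), and Il12a, its other chain, was at 0.815 ± 0.437 and 0.905 ± 0.598 CPM (log2 fold change 0.16, SE 0.61). Cxcl10 had a log2 fold change of -1.06 (SE 0.42), Ebi3 of 0.63 (SE 0.16) and Hlx of 0.49 (SE 0.18). Adjusted over the list alone, Ebi3 rose and Tbx21 fell, and over all genes none passed by edgeR, where 4 had an unadjusted p under 0.05, while DESeq2 called Ebi3.

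Maturation and antigen presentation genes were not called as lists, which does not show that they were alike in both groups. The DC maturation and co-stimulation list had a median log2 fold change of 0.0037 over 25 members (camera adjusted p = 0.743), with 1 member, Tnfsf4, rising and 1, Cd80, falling when adjusted over the list alone. Its mean log2 fold change, -0.0036, and its direction by camera had the opposite sign to its median. Fry's test in either direction gave this list adjusted p = 0.0207, and both antigen presentation lists adjusted p = 0.412. Ccr7, the receptor that guides DCs to the node, was at 5853 ± 471 CPM in adults (SD, n = 3) and 4954 ± 294 CPM in infants (SD, n = 4), a log2 fold change of -0.24 (SE 0.12). Cd40 was at 0.07 (SE 0.14), Cd86 at -0.26 (SE 0.14), Cd80 at -0.70 (SE 0.18), Cd70 at 0.51 (SE 0.18) and Cd274 at -0.59 (SE 0.23). MHC class II presentation had a median of 0.05 (19 members, camera adjusted p = 0.450), with H2-Ob at -0.55 (SE 0.17), Rfxank at 0.42 (SE 0.15), H2-DMb1 at 0.37 (SE 0.16) and H2-DMb2 at 0.41 (SE 0.19). MHC class I presentation had a median of -0.02 (22 members, camera adjusted p = 0.819), with H2-T22 at 0.43 (SE 0.17), Nlrc5 at -0.55 (SE 0.22), Psmb8 at 0.30 (SE 0.14) and Erap1 at -0.27 (SE 0.16). No member of the class I or class II lists passed over the list alone. Over all genes no member of the 3 lists passed by edgeR, where 4, 3 and 2 members of the maturation, class II and class I lists had an unadjusted p under 0.05, while DESeq2 called Tnfsf4 higher and Cd80 lower.

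Interferon genes were lower in infants as lists, with infant 3 apart from the other infants. Its mean centred log2 CPM was 0.32 for interferon-stimulated genes, above every adult (0.029 to 0.18), and 0.21 for the interferon-gamma response, above adult 2 (0.071). The macrophage and monocyte markers, not called as lists, were also highest in infant 3 (0.67 and 0.59) and lowest in infant 4 (-0.50 and -0.66), the infant lowest for both interferon lists (-0.50 for interferon-gamma). For the interferon-gamma response camera gave adjusted p = 0.000168 over 28 members (adjusted p = 0.537 with an estimated correlation), and for interferon-stimulated genes adjusted p = 0.0427 over 32 members (adjusted p = 0.728 with an estimated correlation). No member of either passed when adjusted over the list alone or over all genes by edgeR, where 8 and 5 had an unadjusted p under 0.05. DESeq2 called 1, Irgm1, and over the list alone 4 members of each fell without infant 3. Irgm1 was at -0.86 (SE 0.23), Gbp5 at -0.45 (SE 0.15), Gbp3 at -0.33 (SE 0.12), Trim30a at -0.51 (SE 0.18) and Ifi44 at -0.92 (SE 0.29), while Isg15 was at 0.48 (SE 0.21). The call of interferon-stimulated genes was lost without adult 1, adult 3, infant 1, infant 2 or infant 4 (adjusted p = 0.128, 0.113, 0.334, 0.05004 and 0.269) and under the stricter filter (0.0582), over a range of 1.11e-05 to 0.334 in 24 settings.

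Of the called lists, the one with the smallest camera p and the widest median was that of immediate-early and heat-shock genes, a list set aside to follow cell handling, whose members respond within minutes to stress and stimulation. It was lower in infants (20 members, median log2 fold change -1.03, camera adjusted p = 9.14e-16; adjusted p = 0.0868 with an estimated correlation), and it was the list called by fry (adjusted p = 0.00727). All 20 members had a negative fold change, and 16 fell when adjusted over the list alone, or 10 without infant 1, though over all genes none of the 20 passed by edgeR, where 16 had an unadjusted p under 0.05, and DESeq2 called 7. Fos went from 268 ± 93.8 to 27.9 ± 17.6 CPM, a log2 fold change of -3.26 (SE 0.44, adjusted p = 0.0605 by edgeR). Jun was at -1.04 (SE 0.17), Egr1 at -1.85 (SE 0.33) and Jund at -0.70 (SE 0.13). In 11 of the 20 genes every adult library lay above every infant library. This list moved beside the TNF, cytokine, chemokine, type 2 and GM-CSF lists, and in it and each of these infant 2 had the lowest mean level and every adult library lay above every infant library. The CD11b+ DC markers did so too, and the alveolar macrophage markers, not called as a list, lay between 0.18 and 0.47 in adults and between -0.52 and 0.025 in infants. Some of these lists share members and are not independent. Ptgs2 and Tnf are in the TNF and cytokine lists, and Ccl17 and Ccl22 in the chemokine and type 2 lists. Irf4 and Cd209a are in the type 2 and CD11b+ DC lists.

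Cell-cycle genes were higher in infants (32 members, median 0.46, camera adjusted p = 7.45e-11; adjusted p = 0.447 with an estimated correlation). Of these, 30 had a positive fold change and 12 rose when adjusted over the list alone, with none past the threshold over all genes by edgeR, where 15 had an unadjusted p under 0.05, and 9 by DESeq2. Stmn1 went from 52.9 ± 7.18 to 102 ± 15.98 CPM, a log2 fold change of 0.94 (SE 0.16, adjusted p = 0.152 by edgeR). The mitotic kinase Cdk1 was at 0.96 (SE 0.16), Birc5 at 1.18 (SE 0.24) and the cyclin Ccnb1 at 1.06 (SE 0.22). Mki67, the usual proliferation marker, did not go with them, at 6.27 ± 0.628 CPM in adults (SD, n = 3) and 5.61 ± 1.27 CPM in infants (SD, n = 4), a log2 fold change of -0.16 (SE 0.25). Beside the cell-cycle genes, the B cell gene Ighm was at 262.5 ± 27.7 CPM in adults (SD, n = 3) and 358 ± 119 CPM in infants (SD, n = 4), with 535 CPM in infant 2 and 299 ± 21.4 CPM in the others (SD, n = 3). Oxidative phosphorylation genes were also higher (34 members, median 0.24, camera adjusted p = 2.63e-05; adjusted p = 0.537 with an estimated correlation), with no member past the threshold over the list alone by edgeR, or over all genes by edgeR or DESeq2, and 4 at an unadjusted p under 0.05. Ndufb9 was at 0.32 (SE 0.11), Ndufa1 at 0.40 (SE 0.15), Uqcrq at 0.37 (SE 0.16) and Cox5a at 0.33 (SE 0.13).

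**Figure D4:**
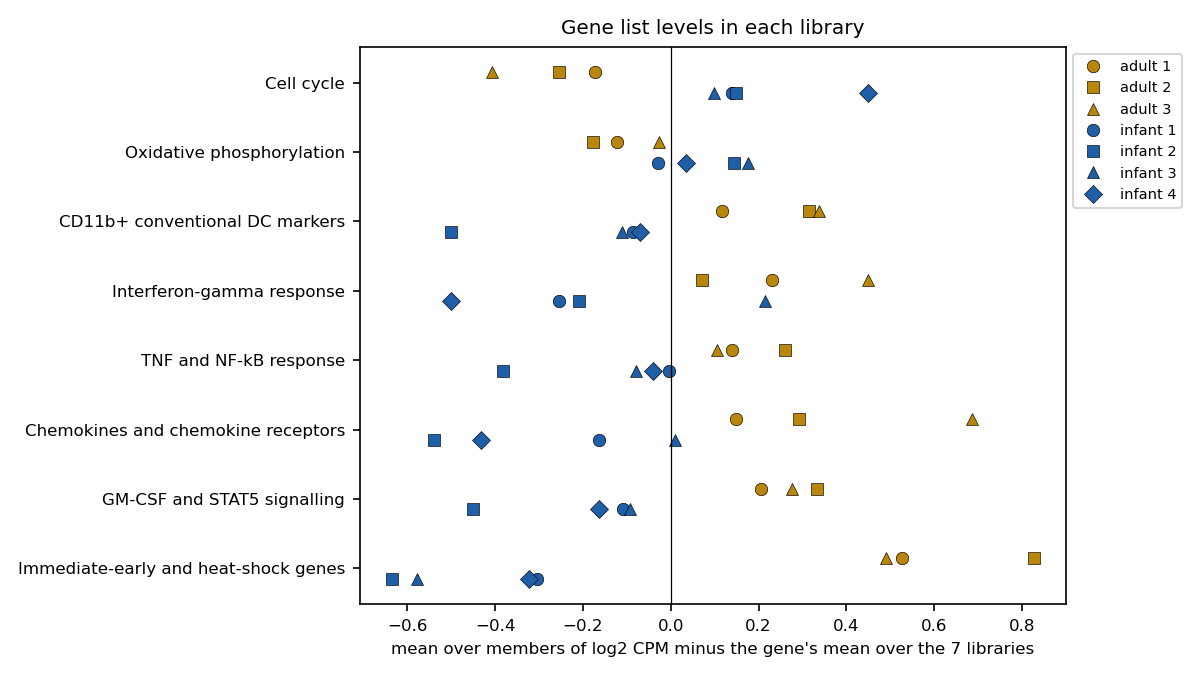
Mean over a list's tested members of log2 CPM minus each gene's mean over the 7 libraries, for 8 lists in each library (adults gold, infants blue; the symbol marks the replicate number). The immediate-early list lies between 0.49 and 0.83 in adults and between -0.64 and -0.31 in infants, and infant 2 is lowest for the CD11b+ DC markers, at -0.50.

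Markers of the sorted cell were lower in infants as a list (CD11b+ conventional DC markers, 14 members, camera adjusted p = 0.000637; adjusted p = 0.494 with an estimated correlation). All 14 had a negative fold change and none passed when adjusted over the list alone by edgeR or over all genes by edgeR or DESeq2, with 2 at an unadjusted p under 0.05 and 1 past the threshold over the list alone without infant 2. Infant 2 was the lowest library for these markers. Zbtb46 was at -0.33 (SE 0.12), Flt3 at -0.65 (SE 0.26), Cd209a at -1.17 (SE 0.54) and Itgax, which encodes CD11c, at -0.50 (SE 0.24). Itgam, which encodes CD11b, is listed as a pair of overlapping entries that can share reads, and the first was at -0.19 (SE 0.26). Of the genes for markers that the gate excluded, Itgae (CD103) was at 2.05 ± 1.03 and 0.844 ± 0.315 CPM. Fcgr1 (CD64) was at 16.1 ± 6.78 and 15.5 ± 10.8 CPM, with 31.6 CPM in infant 3, near the level of the Itgam entry (16.6 ± 0.858 and 14.5 ± 5.27 CPM). Of B and T cell genes, Cd79a was at 1.35 ± 0.689 and 0.717 ± 0.246 CPM, and Cd3e, too low to test, had 2 to 9 reads in adults and 3 to 23 in infants. Ptprc (CD45) was at 681 ± 26.3 and 546 ± 95.2 CPM.

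Among markers of other cells, plasma cell genes were called lower (6 members, camera adjusted p = 0.0424; adjusted p = 0.537 with an estimated correlation), and Prdm1 and Jchain fell when adjusted over the list alone, with none over all genes by edgeR or DESeq2 and 2 at an unadjusted p under 0.05. Prdm1 was at -0.92 (SE 0.26), Jchain at -3.07 (SE 1.01) and Sdc1 at -0.34 (SE 0.26). Jchain rested on adult 3, with 192 of the reads against 26 and 7 in the other adults, and the list's call was lost without adult 3 (adjusted p = 0.431), infant 1 (0.126) or infant 4 (0.120). Under limma-voom, the Y-linked covariate and library quality weights it was also lost (adjusted p = 0.123, 0.0520 and 0.160). Over 24 settings its adjusted p could be had in 21 and ran from 0.00398 to 0.431. The B cell list was not called (12 members, adjusted p = 0.819), and Igkc, at -2.79 (SE 0.81), again rested on adult 3, with 2271 reads against 256 and 179.

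No other cell type list was called by camera, and over all genes none of their members passed by edgeR, where 14 had an unadjusted p under 0.05 and DESeq2 called Cd8a, Adgre1 and Marco. Fry's test in either direction passed for the B cell markers (adjusted p = 0.0203) and the alveolar macrophage markers (adjusted p = 0.00705). Adjusted over the list alone, Cd8a rose in the T cell and CD103+ DC lists, Adgre1 in the macrophage list and Cd37 in the B cell list, while Igkc, Marco, Fabp4, Lcn2, Kit and Kdr fell in theirs. The adjusted p was 0.149 for T cell markers (Cd8a at 0.83, SE 0.20), 0.0677 for NK and cytotoxic cells (Nkg7 at -1.09, SE 0.41), 0.864 for macrophages (Adgre1 at 0.50, SE 0.13) and 0.743 for monocytes (Fn1 at -0.65, SE 0.40). It was 0.0946 for alveolar macrophages (Marco at -1.78, SE 0.43), 0.913 for CD103+ DCs and 0.782 for plasmacytoid DCs (Atp1b1 at 0.88, SE 0.31). The B cell list had a negative median (-0.09) and a positive direction by camera, and the T cell list a median of 0.27. Neutrophil, eosinophil with basophil and mast cell, epithelial, endothelial and stromal markers had 3 or 4 tested members each, too few for the list test, and erythroid markers had 0. Their leading members were Lcn2 (-2.18, SE 0.64), Kit (-0.77, SE 0.26), Muc1 (0.53, SE 0.52), Kdr (-1.18, SE 0.26) and Ccl21a (1.48, SE 0.77). Over all genes none of the members passed by edgeR, where 4 had an unadjusted p under 0.05, while DESeq2 called Lcn2 and Kdr.

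The remaining lists were not called, and no member passed over the list alone by edgeR in those tested, where 15 had an unadjusted p under 0.05 and DESeq2 called Atf3 and Marco over all genes. Camera gave an adjusted p of 0.450 for glycolysis (Pfkp at -0.51, SE 0.15), 0.662 for cholesterol and lipid synthesis (Scd1 at -1.29, SE 0.46), 0.479 for the unfolded protein response (Atf3 at -1.25, SE 0.32) and 0.112 for phagocytic and pattern-recognition receptors. Cytosolic ribosomal proteins had 0.501, mitochondrially encoded genes 0.112 and the list of Y-linked genes with Xist 0.245. The list of juvenile growth and imprinted genes had 4 tested members, of which Igf2bp3 rose.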

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

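All tests of explanations in this part, the counts over other splits of the libraries included, were chosen only after the results were seen, while the rule for a library far from its group was set beforehand. In groups of 4, a library was picked out where its gap to the nearest other as a share of the group's range passed Dixon's 95% critical value, which chance does in about 1 in 20 groups (5%). Of 148 groups of infant libraries 14 (9.46%) met this, 7 of them through infant 2, and the 3 adults are too few for the rule.

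Infant 2 had 98.1% of its reads in protein-coding genes against 98.99% in each of the others, and 13539 CPM of Malat1 against 3108 to 3728, 535 CPM of Ighm against 281 to 323 and 2.73 CPM of Arid3a against 3.53 to 3.67. On the mean centred log2 CPM of a list, infant 2 lay at -0.22 for MHC class I presentation, -0.42 for cholesterol and lipid synthesis and -0.50 for the CD11b+ DC markers. Infant 3 had 7.18 CPM of Ifi44, 31.6 CPM of Fcgr1, and list means of 0.32 for interferon-stimulated genes and 0.26 for glycolysis. Infant 4 had 17.7 CPM of Cdk1 and a list mean of 0.45 for the cell cycle. Infant 1 had a list mean of -0.47 for the B cell markers.

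The immediate-early and heat-shock genes were lower in infants, and of the 35 splits of the 7 libraries into 3 and 4 only 1, the real one, gave a camera p as small (2.86e-17, next 6.05e-17). The next p came from the split of infants 1, 3 and 4 from the rest. That split differs from the real one only in the place of infant 2, so its close p says little about chance. The list was singled out for the smallest p of 32, so chance is not taken as excluded. Infant 2 alone is argued against, since the median log2 fold change without it was -0.91. A response to handling during isolation stays open: the 6 heat-shock members had a median of -0.62, and any handling difference cannot be told apart from age, since the labels give no isolation batch. An effect of age itself is open too and was not tested.

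The cell-cycle genes were higher in infants, and 2 of the 35 splits gave a camera p as small (4.66e-12, best other 4.36e-12). The other split set infants 1, 2 and 4 apart and differs from the real one only in the place of infant 3. Its p is therefore no sign of chance by itself. A share of 2 in 35 is still too large to exclude chance. Infant 2 alone is argued against, with a median of 0.42 without it. Cycling T cells in the sort are argued against, since the summed rise of their receptor complex genes came to 0.206% of the list's rise in CPM, though Cd8a, which DCs also express, went from 24.8 to 44.0 CPM. Cycling B cells stay open, since the B cell receptor genes with Ighm came to 44.9% of that rise, though to 20.8% without infant 2, which had 535 CPM of Ighm, and to 4.19% without Ighm, and the sort removed B220+ cells. Other dividing cells, and an effect of age, stay open.

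Igf2bp3 was higher in infants, and none of the other 34 splits called a gene. This argues against chance at 1 of 35, the smallest share the splits allow. The test was chosen after the gene was seen to separate the groups, so chance is not taken as excluded. Reads shared with copies are argued against, since 92.7% of its infant exon reads mapped uniquely. The mix of sexes in the libraries is argued against, since its log2 fold change was 7.25 with the level of Y-linked genes as a covariate. Reads of the overlapping plus-strand genes are argued against as the source, since 71.8% of the infant exon reads (978 of 1363) crossed an exon junction. Malsu1 stood at 20.8 CPM in adults where Igf2bp3 was at 0.198 CPM, and Gm18010 had 0 reads. In infants Malsu1 stood at 33.0 ± 5.49 CPM (SD, n = 4). An effect of age stays open.

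The count of 2 changed genes was reached by 1 of the 35 splits, the real one, as were the count of 1 higher and that of 1 lower (highest other 0). That is the smallest share the splits allow, in a test chosen after the results were seen. It argues against chance for these edgeR counts without excluding it, and it does not extend to the count by DESeq2 given last. The count of 12 called lists was reached by 12 splits (highest other 19), so chance cannot be excluded for it. For GM-CSF and STAT5 signalling 1 split, the real one, had a p as small (9.30e-05, best other 0.000246). That best other split set infants 1, 2 and 4 apart, and differs from the real one only in the place of infant 3. Of the 32 lists, 2, the GM-CSF and the immediate-early one, had their smallest p in the real split. Chance gives 0.914 lists a split and another split had 6, so chance is not taken as excluded for either. It cannot be excluded for TNF and NF-kB (7 splits, 0.00523, best other 0.000765), type 2 associated genes (8, 0.00145, 5.27e-05), inflammatory cytokines (4, 0.000876, 6.77e-07), chemokines (5, 8.41e-07, 1.33e-11) and interferon-gamma (8, 2.63e-05, 3.25e-13). Nor can it for interferon-stimulated genes (20, 0.0160, 1.63e-15), oxidative phosphorylation (3, 3.29e-06, 3.26e-07), CD11b+ DC markers (3, 0.000139, 7.19e-05) and plasma cells (9, 0.0146, 0.000875). The 1626 genes at an unadjusted p under 0.05 were reached by 2 of the 35 splits (highest other 2586), as were the 181 DESeq2 calls (highest other 576), so chance cannot be excluded for these counts. Both of those highest counts came from the split of infants 2, 3 and 4 from the rest, which points to a structure of the samples. That split differs from the real one only in the place of infant 1, and whether the structure is other than age was not tested.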

How the results depend on the processing

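Chosen only after the data were seen were the Y-linked covariate, the quality weights and the thinned counts. Igf2bp3 passed in all 24 settings and Rnf217 in 20 of the 22 that gave it a value. Of 823 values of lists 711 kept direction and call, 38 lost the call, 26 gained it and 48 reversed, and of 2497 values of named genes 2427 kept both, 2 lost the call, 54 gained it and 14 reversed. Every reversal was of a list or gene not called by the edgeR fit reported, and 1 was past the threshold where it turned: the Y-linked genes with Xist under the Y-linked covariate, which is made from 4 of that list's genes. The cause of the others was not tested. The number of changed genes, 2, was 181 by DESeq2 (66 higher, 115 lower), 8 with no filter (7 lower), 1 in each of the 3 settings on RPKM (0 lower), 121 with quality weights (59 higher, 62 lower) and 2 to 10 leaving out 1 library (1 to 2 higher, 1 to 9 lower). Genes lower in infants numbered 2 by limma-voom and 2 with the Y-linked covariate. The lists called numbered 0 with an estimated correlation and 1 by fry. With the replicate number as a block 1 gene passed (0 lower). The labels do not say whether the numbers pair the samples. Same-numbered libraries had correlations of deviations of 0.0332, -0.0345 and 0.101. These lie within the -0.185 to 0.150 of differently numbered ones, and so few values cannot settle it. The block also ended the calls of interferon-stimulated genes (adjusted p = 0.141) and plasma cells (0.155). In it these turned direction: CD103+ DCs (0.552), plasmacytoid DCs (0.573), macrophages (0.739), monocytes (0.683), ribosomal proteins (0.690), the Y-linked genes with Xist (0.739), Tlr4 (log2 fold change 0.044) and Fcgr1 (0.033). CD103+ DCs also turned by DESeq2 (0.928), voom (0.877), no filter (0.832), the stricter filter (0.628), RPKM with a pseudocount of 1 (0.449), of 0.1 (0.450) or no filter (0.782), quality weights (0.834), thinned counts (0.998) and an estimated correlation (0.995). Macrophages turned by DESeq2 (0.945), no filter (0.875) and the stricter filter (0.737), B cells with no filter (0.967) and RPKM with no filter (0.992), and plasmacytoid DCs by fry (0.970). The Y-linked genes with Xist turned by voom (0.175), the Y-linked covariate (0.00544), quality weights (0.402), an estimated correlation (0.728) and fry (0.668). With quality weights DC maturation (0.835), MHC class I (0.602) and Il12a (log2 fold change -0.13) turned. Leaving out 1 library, the adjusted p ran over 0.267 to 0.948 for CD103+ DCs, 0.0264 to 0.990 for macrophages, 0.555 to 0.992 for B cells, 0.550 to 0.921 for plasmacytoid DCs, 0.0856 to 0.950 for monocytes, 9.03e-07 to 0.990 for ribosomal proteins, 0.490 to 0.954 for DC maturation, 0.550 to 0.990 for MHC class I, 0.0455 to 0.948 for cholesterol, 0.00202 to 0.990 for NK cells and 0.0129 (without adult 2) to 0.512 for the Y-linked genes with Xist, which kept their direction there. The log2 fold change then ran over -0.70 to 0.14 for Tlr4, -0.67 to 0.30 for Fcgr1, -0.36 to 0.63 for Il12a, -0.69 to 0.030 for Igf2bp2 and -0.0042 to 0.12 for Cd40. Depth limits low genes, since 3 reads are 0.134 to 0.167 CPM before TMM scaling.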

Other observations

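The hypothesis and its test in this part were chosen only after the level of Igf2bp3 was seen. Of the 18 juvenile growth and imprinted genes fixed beforehand 4 could be tested, and Igf2bp3 rose while Cdkn1c, a cell-cycle inhibitor expressed from 1 parental copy, was at 1.64 ± 0.562 CPM in adults (SD, n = 3) and 2.73 CPM in infants (n = 4), a log2 fold change of 0.74 (SE 0.39, adjusted p = 0.420 by edgeR). The others, named after their values were seen, were Igf2bp2, of the same family as Igf2bp3, with a log2 fold change of -0.38 (SE 0.89), and Arid3a with -0.22 (SE 0.25). Igf2, the growth factor whose mRNA the family of Igf2bp3 binds, had 1 read in adult 2 and 1 in infant 2, and H19 had 0 reads in every library.

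A hypothesis was that Igf2bp3 may be part of a wider fetal-type programme in infant cells. In infants Hmga2 had 1 read in infant 2 and 2 in infant 4, and Lin28b and Igf2bp1 had 0. The summed infant CPM of these 3 genes was 0.0398, against 17.9 CPM of Igf2bp3. That sum is below the 0.134 to 0.167 CPM that 3 reads stand for before TMM scaling. This argues against a programme that includes these 3 genes at a like level, and fetal-type genes outside these were not tested.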
